A study of Mus musculus with 20 samples.

How the data were processed

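Liver RNA of male C57BL/6J mice was measured on 20 Affymetrix expression arrays after long exposure to 137Cs gamma rays. Per the labels' protocols, the first experiment lasted 485 days with dose-rates of 0.042, 0.858 and 16.6 mGy per day, and the second lasted 401 days with 0.05, 1.00 and 20.0 mGy per day. These 3 dose-rates are called low, medium and high here. Each of the 6 irradiated groups had 3 arrays of 1 mouse each, and each experiment had 1 control array of RNA pooled from unirradiated mice, 3 mice in experiment 1 and 6 mice in experiment 2. Livers were taken as soon as irradiation ended, kept in RNAlater and extracted with ISOGEN, and biotinylated cRNA was hybridized, per the labels' protocols. The time of day at which mice were killed is not given in the sources used here.

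The deposited values are MAS5 signal intensity on a linear scale, made by the authors per the submitters' processing notes, and the MAS5 version is not given in the sources used here. The mean signal after trimming 2% at each end was 500.0 on every array, so the arrays had been scaled to a common level. Array medians ran from 81.3 to 104.8 and values from 0.125 to 100765. The table held 45101 probe sets on 20 arrays, with 0 columns that belonged to no sample. Gene names came from the platform annotation. It gave 1 gene symbol for 34945 probe sets (18193 genes), several for 932 and none for 9160, and the other 64 were array controls. Of 34741 probe sets whose gene identifier was in the current reference table, 0 needed a newer symbol. No pair of arrays held identical values, and the highest correlation between 2 arrays was 0.943.

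Signals were used as scaled by the authors and transformed as log2(signal + 7.12), where 7.12 is the 10th percentile of all signals. Fold changes are on that scale, which understates the change of genes with low signal. Probe sets with a mean at or above the median of all probe sets were kept (22519), and 1 probe set per gene was used, those not ending in _s_at or _x_at first and then the one with the highest mean, which left 11216 genes. The main model was a linear model of limma 3.58.1 (lmFit and eBayes with a variance trend) in R 4.3.3, fitted to all 20 arrays with dose level and experiment as terms, 15 residual degrees of freedom, two-sided contrasts and Benjamini-Hochberg adjustment at 0.05. All arrays share 1 estimate of the spread because a single pool has none of its own. The difference of an effect between experiments was tested as an interaction. Per-gene errors are standard errors of the contrast, signals are means ± SD over mice, and p-values measure the spread between these samples, which were 1 mouse each among the irradiated and pools of several mice among the controls. The number of arrays limits the precision, above all in contrasts with control, which rest on 2 pools. A second rule counted genes at least 1.5-fold from the pool of their own experiment in all 6 mice of a level.

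Lists of 24 pathways and 17 cell types were fixed before the data were examined, as were the groups, the models, the rule for naming genes and all alternatives except those named as added. Of 910 list symbols, 820 were on the array. Each list was tested with camera of limma at a preset correlation of 0.01, adjusted over the 41 lists within a contrast. Beside it stand camera with an estimated correlation and fry. The directional p of fry tests whether the genes of a list move one way on balance, and its mixed p whether they change in either direction, and neither compares the list with other genes. Members were counted past the threshold over all genes and adjusted over the list alone.

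Genes were named by rule. For high against control and high against low these were the 10 largest rises and the 10 largest falls past the threshold with the same sign in both experiments, and where fewer than 5 passed in a direction the places up to 5 went to the smallest unadjusted p, named as not passing. For the other contrasts between levels the numbers were 5 and 3. For each interaction the 3 genes with the smallest p were named, for the 1.5-fold rule the 5 highest and the 5 lowest of each level, and for a called list or one with a member past the threshold up to 4 members with the smallest p, and for other lists up to 2. A disagreement in sign between probe sets of a named gene is stated. Genes named outside the rule are said to be so. Counts of mice with the same direction set each mouse against the pool of its experiment in contrasts with control. Between dose levels they set each mouse of the first level against the mean of the second level in its experiment. Such a count does not mean that the mice of the 2 levels were separate.

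The procedure was tested on simulated data drawn from the real means and spreads. For high against control, 65 of 100 genes changed 2-fold and 88 of 100 changed 4-fold were recovered, with 6 false calls among 11216 genes. For high against low, the numbers were 80 and 98 of 100, with 16 false calls. A list moved by 0.4 was recovered in both, with 0 false lists of 41. Genes were drawn independently of each other there, so false list calls among correlated genes were not tested by it. Splits of the real mice that ignore dose, described below, gave a median of 8 called lists for high against low.

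Alternatives tried were the filter, the pseudocount, scaling between arrays, every probe set on its own, the arrays and terms of the model, array weights, weights for the pools, a replicate block, the threshold, the variance trend, the averaging of mice on the linear scale and leaving out each array. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for reading and drawing, and statmod 1.5.0 for the random block. Probe sets with several genes or none entered only the alternative over every probe set. A test for outlying samples was not made, because no group had more than 3 arrays.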

Results

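Gene expression was compared between livers of unirradiated mice and of mice that had lived for 485 days (experiment 1) or 401 days (experiment 2) under gamma rays at 1 of 3 dose-rates. Cumulative doses were 20.6, 416 and 8030 mGy at the low, medium and high dose-rate of experiment 1 and 20, 401 and 8015 mGy in experiment 2. Each level had 6 mice, 3 per experiment, on 1 array each, and each experiment had 1 control array of pooled RNA. After scaling, the 75th percentile of signal lay between 358.8 and 397.3 on all 20 arrays. The experiments differed more than the dose levels did. The first principal component separated them with 25.6% of the variance, and limma called 4761 of 11216 genes between them, 3122 higher and 1639 lower in experiment 2. The ratio of 3' to 5' signal of Gapdh, a measure of RNA integrity, was 0.69 to 0.769 in experiment 1 and 0.871 to 0.993 in experiment 2. All contrasts below were therefore taken within experiment.

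The first comparison asked which liver genes differ between mice at the high dose-rate and unirradiated mice. Ccdc8, a component of the 3M complex that keeps microtubules and the genome intact, rose by 2.06 ± 0.34 on the log2 scale (SE, 6 mice against 2 pools, adjusted p = 0.02 by limma), from signals of 13.9 and 35.8 in the pools to 121 ± 31.3 (SD, n = 6). The RIKEN transcript C730049O14Rik rose by 0.97 ± 0.15 (adjusted p = 0.0126), and Rnf125, a ubiquitin ligase, rose by 0.83 ± 0.11 (adjusted p = 0.00373). Angptl4, a secreted inhibitor of lipoprotein lipase, fell by 1.61 ± 0.30 (adjusted p = 0.0378), from 4782 and 6124 in the pools to 1822 ± 478.5. St3gal5, which makes the ganglioside GM3, fell by 1.07 ± 0.18 (adjusted p = 0.0229), and Lpin2, a phosphatidate phosphatase, fell by 0.76 ± 0.14 (adjusted p = 0.0295), with 1 of 3 other probe sets of Lpin2 in the opposite direction. The pool signals of Ccdc8 lay under the array medians (81.3 to 104.8) and are not shown to be above background, so the size of its rise is uncertain. For Ccdc8, high against control, a pseudocount at the 25th percentile gave 1.54 (adjusted p = 0.0395). These were the 6 genes past the threshold, 3 higher and 3 lower. Each differed from the pool of its experiment in the same direction in 6 of 6 mice. The difference of Ccdc8 was 2.39 in experiment 1 and 1.74 in experiment 2, and that of Angptl4 was -1.51 and -1.71. In total 805 genes had an unadjusted p under 0.05, against 561 that chance alone gives on average. With no experiment term 3 genes passed, all higher, and without a variance trend also 3, all higher. Neither fit called Angptl4, St3gal5 or Lpin2.

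Genes next in order did not pass. Zbtb16, a transcription factor induced by glucocorticoids, was -2.24 ± 0.43 from control (adjusted p = 0.0614), and Herpud1, which acts in degradation of misfolded proteins of the endoplasmic reticulum, was -0.97 ± 0.20 (adjusted p = 0.106), both lower in 6 of 6 mice. Nova2 (adjusted p = 0.106) and Ssr4 (adjusted p = 0.103) were higher in 6 of 6 mice. Their sizes are not given, since the signal was 20.6 for Nova2 in the experiment 1 pool and 53.2 for Ssr4 in the experiment 2 pool, and another probe set of Ssr4 went the opposite way. Without the control pool of experiment 1, none of the 6 called genes passed and Ssr4 did (adjusted p = 0.0104), against a signal of 53.2 in the remaining pool that is not shown to be above background, whereas 24 genes passed without the pool of experiment 2. For Angptl4, high against control, the call also ended without the experiment 2 pool (adjusted p = 0.114), with no filter (0.978, another probe set), without a variance trend (0.145) and, with adjusted p from 0.0516 to 0.0916, without high mouse 2 of experiment 1, high mouse 2 or 3 of experiment 2, medium mouse 1 or 2 of experiment 1, medium mouse 2 or low mouse 3 of experiment 2. With median-centred arrays 3 genes passed, 1 higher and 2 lower, weighting each pool by its number of mice gave 360, and neither experiment alone gave any.

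**Figure D1:**
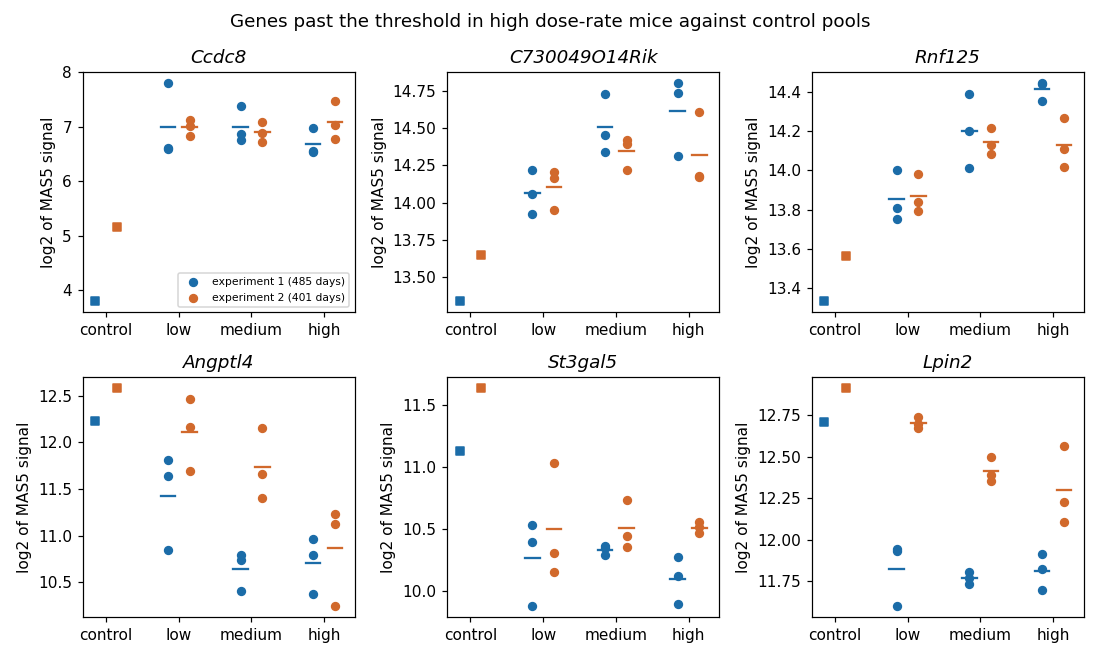
Log2 of MAS5 signal for the 6 genes past the threshold in high dose-rate mice, by dose level. Squares are control pools (1 array per experiment), circles are single mice, bars are means of 3 mice, and the colour gives the experiment. Ccdc8 lay at signals of 13.9 and 35.8 in the pools and at 92.3 or above in all 18 irradiated mice.

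Among gene lists in the same comparison, the circadian clock list held the most members that passed when adjusted over the list alone, 9 of 19 (2 higher, 7 lower), and 0 passed over all genes. Usp2, a clock-driven deubiquitinase, was -1.74 ± 0.36, Dbp, a clock output transcription factor, was -1.55 ± 0.36, Tef was -0.52 ± 0.12 and Nr1d2 was -0.36 ± 0.09, each lower in 6 of 6 mice. Arntl, which encodes the clock activator BMAL1 and peaks in the opposite phase, was 0.97 ± 0.27 (named after its value was seen). The list as a whole was called lower (median -0.34, camera adjusted p = 0.00075; adjusted p = 0.063 with an estimated correlation), and fry gave an adjusted p of 0.02 for a common direction and 5.7e-06 for change in either direction. Of 20 heat shock response genes, which encode chaperones, 15 were lower (median -0.40, or -0.20 without the experiment 1 pool, adjusted p = 1.2e-06; adjusted p = 0.7 with an estimated correlation), and 6 passed adjusted over the list alone, with Hspa1b at -1.93 ± 0.57 and Stip1 at -0.59 ± 0.20. The signal of Hspa1b was 5454.2 in the pool and 446 to 943.4 in high mice of experiment 1. In experiment 2 it was 1945.3 and 720.2 to 1305.5, a smaller fall. For another gene of this list, Hspa8 (-0.74 ± 0.22), 1 of 3 other probe sets went the opposite way. Genes of ER stress and amino acid response were called lower (median -0.25, 20 of 24 lower, adjusted p = 0.00023; adjusted p = 0.84 with an estimated correlation). Herpud1 and, in the opposite direction, Atf4 (0.53 ± 0.14) passed adjusted over that list alone.

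The interferon response list, genes induced by antiviral signalling, was called higher (30 of 32 higher, median 0.48, adjusted p = 2e-09; adjusted p = 0.75 with an estimated correlation). Its median was 0.24 without the experiment 1 pool, 0.80 in experiment 1 alone and 0.17 in experiment 2 alone. None of its members passed, over all genes or adjusted over the list alone, while 10 had an unadjusted limma p under 0.05. Oasl1 was 1.10 ± 0.35 and Rtp4 1.09 ± 0.39 above control in 6 of 6 mice. Cholesterol synthesis genes were called higher (19 of 20, median 0.39, adjusted p = 9.3e-06; adjusted p = 0.75 with an estimated correlation), with Hmgcs1, the synthase that feeds the mevalonate pathway, at 0.63 ± 0.18 as the 1 member past the threshold adjusted over the list alone, and Sqle, squalene epoxidase, at 1.51 ± 0.52. Smaller shifts were called for oxidative phosphorylation (median 0.09, or 0.06 without high mouse 2 of experiment 1, adjusted p = 0.00017; adjusted p = 0.84 with an estimated correlation) and extracellular matrix (median 0.17, adjusted p = 0.01; adjusted p = 0.84 with an estimated correlation), the latter with Sparc at 0.56 ± 0.20. All 17 male-biased liver genes were lower (median -0.29, adjusted p = 0.0042; adjusted p = 0.84 with an estimated correlation), with Ugt2b38 at -1.80 ± 0.79. The list of fatty acid oxidation and PPAR alpha targets was not called (median -0.05, adjusted p = 0.16), but Angptl4, Acot1 (-0.96 ± 0.25) and Creb3l3 (-0.35 ± 0.10) passed adjusted over that list alone, Angptl4 also over all genes. Without the experiment 1 pool the extracellular matrix list (median 0.21, adjusted p = 0.281) and the male-biased list (median -0.17, adjusted p = 0.349) were not called, nor was cholesterol synthesis without the experiment 2 pool (median 0.24, adjusted p = 0.0722). The oxidative phosphorylation call was lost with median-centred arrays (adjusted p = 0.116). In experiment 2 alone oxidative phosphorylation (median 0.04, adjusted p = 0.211), extracellular matrix (0.15, 0.252) and male-biased genes (-0.28, 0.235) were not called.

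**Figure D2:**
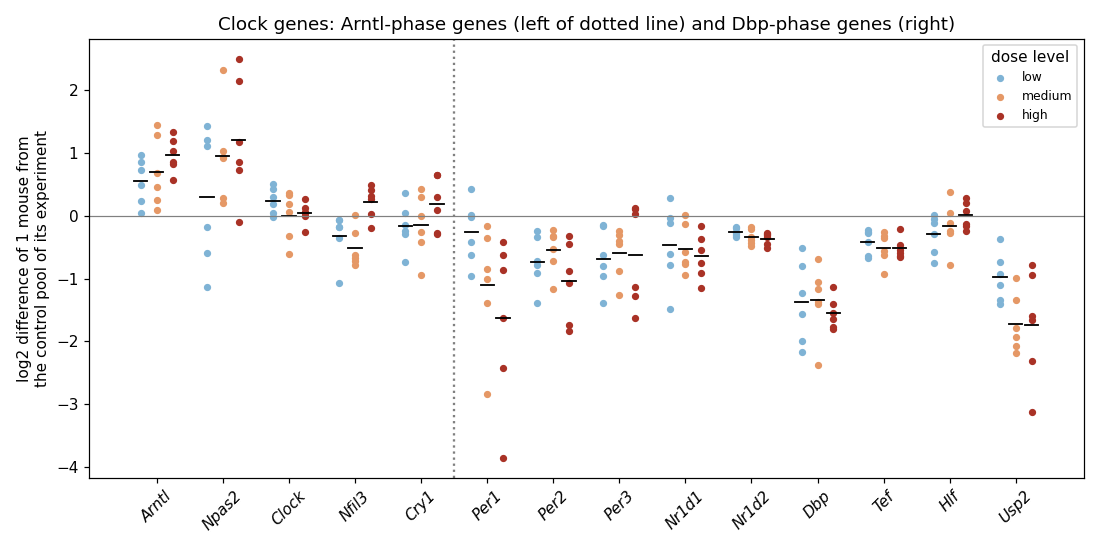
Log2 difference of each irradiated mouse from the control pool of its experiment for clock genes, coloured by dose level, with bars at the mean of 6 mice. Left of the dotted line are genes grouped with Arntl and right of it genes grouped with Dbp. Peak times were not measured here. Dbp and Usp2 lay below the pools in all 18 mice, and Arntl lay above them in all 18.

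At the medium dose-rate 3 genes passed, all higher than control in 6 of 6 mice and all among those called at the high dose-rate. Ccdc8 rose by 2.12 ± 0.34, C730049O14Rik by 0.93 ± 0.15 and Rnf125 by 0.73 ± 0.11 (adjusted p = 0.0159 for each, limma). Lpin2 (-0.72 ± 0.14, adjusted p = 0.0686) and St3gal5 (-0.96 ± 0.18, adjusted p = 0.0812) did not pass, nor did Usp2 (-1.72 ± 0.36, adjusted p = 0.183), all lower in 6 of 6 mice. An unadjusted p under 0.05 was found for 671 genes. None of the 3 genes passed without the experiment 1 pool, where 1 other gene did, and 22 genes passed without the experiment 2 pool. Weighting the pools by their mice gave 260 genes and median-centred arrays gave 1. For Ccdc8, medium against control, a pseudocount at the 25th percentile gave 1.59 (adjusted p = 0.0531).

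The circadian clock list was lower in medium dose-rate mice (median -0.34, adjusted p = 1.9e-05), and this call held with an estimated correlation (adjusted p = 0.0079). Usp2, Dbp (-1.34 ± 0.36), Tef (-0.51 ± 0.12) and Nr1d2 (-0.34 ± 0.09) passed adjusted over the list alone, and 0 of its 19 members passed over all genes. Heat shock response genes were called lower (15 of 20, median -0.34, or -0.15 without the experiment 1 pool, adjusted p = 3.6e-06; adjusted p = 0.63 with an estimated correlation), and 6 of them passed adjusted over the list alone, among them Chordc1 (-0.57 ± 0.15) and Stip1 (-0.65 ± 0.20). ER stress genes were called lower (median -0.30, adjusted p = 0.00011; adjusted p = 0.86 with an estimated correlation), with Herpud1 (-0.93 ± 0.20) past the threshold adjusted over the list alone. Fatty acid oxidation and PPAR alpha targets were called lower (27 of 36, median -0.11, or -0.07 without medium mouse 3 of experiment 1, adjusted p = 0.00011; adjusted p = 0.94 with an estimated correlation). Angptl4 (-1.21 ± 0.30), the thioesterase gene Acot1 (-0.98 ± 0.25) and Hsdl2 (-0.42 ± 0.11) passed adjusted over that list alone. With no filter Angptl4 was read from another probe set, which went the opposite way. Lists called higher were cholesterol synthesis (median 0.28, adjusted p = 0.016), extracellular matrix (0.19, 0.022), oxidative phosphorylation (0.07, 0.0047), hepatocyte markers (0.11, 0.022) and B cell markers (0.58, 0.021). With an estimated correlation their adjusted p values were 0.98 for the first 4 and 0.63 for B cell markers. Members with the smallest p were Sc5d (0.38 ± 0.14), Mmp2 (pool signals 65.1 and 219.8), Ndufv2 (0.16 ± 0.09, 1 of 2 other probe sets opposite), Apoa1 (0.21 ± 0.09) and Ms4a1 (pool signals 70.0 and 74.6), and 0 members of these 5 lists passed adjusted over the list alone. Unadjusted p values under 0.05 were held by 2, 2, 0, 1 and 0 of their members. The calls for these 5 lists each ended without 1 or more single arrays, with adjusted p up to 0.696 for cholesterol synthesis without the experiment 2 pool (median 0.12) and 0.505 for hepatocyte markers without the experiment 1 pool (median 0.07). For the extracellular matrix the highest was 0.412 without the experiment 1 pool, and its median was 0.12 without medium mouse 3 of experiment 2, for B cell markers 0.167 without the experiment 2 pool and for oxidative phosphorylation 0.0647 without medium mouse 2 of experiment 2. Hepatocyte markers turned to lower with quantile normalization (adjusted p = 0.925). In experiment 1 alone cholesterol synthesis (median -0.04, adjusted p = 0.844), B cell markers (0.36, 0.39), extracellular matrix (0.19, 0.125) and oxidative phosphorylation (0.08, 0.0848) were not called. In experiment 2 alone hepatocyte markers (0.09, 0.499) were not, nor were heat shock (-0.15), ER stress (-0.18) and extracellular matrix genes (0.23) (adjusted p = 0.055 for each).

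At the low dose-rate Ccdc8 was the 1 gene past the threshold. It rose by 2.17 ± 0.34 (adjusted p = 0.03, limma, higher in 6 of 6 mice), from the same low pool signals to a signal of 133 ± 47.3 (SD, n = 6). St3gal5 was -0.99 ± 0.18 (adjusted p = 0.125) and lower in 6 of 6 mice. Casp14 (1.15 ± 0.23) and Ssr4 were higher in 6 of 6 mice (adjusted p = 0.136 for each), with the other probe set of Ssr4 opposite and its signal at 53.2 in the experiment 2 pool. Lpin2 (-0.55 ± 0.14) and Fam214a (-0.64 ± 0.16) had adjusted p values of 0.55. Unadjusted p values under 0.05 numbered 429, fewer than the 561 of chance. For Ccdc8, low against control, the call ended without the experiment 1 pool (1.70 ± 0.44, adjusted p = 0.501), with no filter (0.0921), with the top 30% of probe sets, with a pseudocount at the 25th percentile (1.64, adjusted p = 0.11) and with only the 2 levels compared (0.999). It also ended, with adjusted p from 0.0501 to 0.0692, without medium mouse 1 or 3 of experiment 1 or low mouse 2, medium mouse 1 or 2 or high mouse 2 or 3 of experiment 2, and 12 genes passed without the experiment 2 pool. Weighting the pools by their mice gave 56 genes, 34 higher and 22 lower.

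Fatty acid oxidation and PPAR alpha targets were called lower in low dose-rate mice (33 of 36 lower, median -0.16, or -0.10 without low mouse 2 of experiment 1, adjusted p = 2.1e-08; adjusted p = 0.63 with an estimated correlation). The members with the smallest p were Acot1 (-0.89 ± 0.25), the carnitine palmitoyltransferase Cpt1a (-0.44 ± 0.14) and the nuclear receptor Ppara itself (-0.56 ± 0.18), each lower in 6 of 6 mice. None passed adjusted over the list alone, and 8 had an unadjusted limma p under 0.05. The circadian clock list was lower (16 of 19, median -0.29, adjusted p = 1.7e-05), a call that held with an estimated correlation (adjusted p = 0.0076), and Dbp (-1.38 ± 0.36), Tef (-0.42 ± 0.12) and the repressor Cry2 (-0.60 ± 0.20) passed adjusted over the list alone. Over the 6 contrasts between levels, 45 list calls were made. With an estimated correlation the clock calls at the medium and low dose-rates held and the other 43 were lost, and the directional test of fry passed for the clock list in all 3 contrasts with control and for none of the other 42.

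By the rule of 1.5-fold in all 6 mice, 45 genes differed from their pools at the high dose-rate (26 higher, 19 lower), 34 at the medium (21 and 13) and 18 at the low (16 and 2). Simulated groups without any effect gave 28.4 genes on average and 39 at most when a pool varied like 1 mouse, and 2.84 on average and 9 at most when its variance was divided by its number of mice. Ccdc8, Git1 and St3gal5 met the rule at all 3 levels, and 12 genes were shared by medium and high. Below control at the high dose-rate the rule named Obp2a, an odorant-binding lipocalin (-2.50 ± 0.97), Zbtb16, Usp2, Serpina4-ps1 (-1.63 ± 0.73) and Angptl4. At the medium dose-rate it named Obp2a (-2.42 ± 0.97), Cphx3, Zbtb16 (-1.70 ± 0.43), Usp2 and the cell cycle factor E2f8, and at the low dose-rate Poc5 and St3gal5. The mean signal was 47.9 for Cphx3 and 89.0 for E2f8 in medium mice and 64.4 for Poc5 in low mice. Above control, beside Ccdc8, it named Hebp2, the hair keratin-associated Krtap3-1, Ctxn1 and 0610040F04Rik at the high, Nkx2-6, Cldn22, Adamts5 and Adcy5 at the medium and Krtap3-1, Cldn22, Git1 and Chrna4 at the low dose-rate. Signals of these genes in 1 or both pools lay under the array median, such as 6.3 and 73.7 for Hebp2 and 31.4 and 23.4 for Krtap3-1. All of these signals are under or near the array medians and not shown to be above background, so sizes are not given. Another probe set of Adamts5 and of Adcy5 went the opposite way. Of the genes in this paragraph, Ccdc8 at all 3 levels and Angptl4 and St3gal5 at the high dose-rate passed limma's threshold.

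The 3 contrasts with control share the same 2 pools. Across genes, which are not independent replicates, the fold changes of high and medium correlated with r = 0.781, of high and low with 0.665 and of medium and low with 0.703. Simulated groups without effect against shared pools, each pool varying like 1 mouse, gave 0.75, 0.75 and 0.749. The covariance exceeded the simulated one by 0.0093 for high and medium (SD of the simulated covariance 0.0021), and was -0.0068 and -0.0072 from it in the pairs with low. If a pool varies like 1 mouse, fold changes that share pools correlate to about this degree without any effect. The smaller variance of RNA pooled from several mice was not simulated here. These correlations therefore cannot show how much of the agreement comes from the shared pools, and the 2 pools are too few to split.

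The comparison of high with low dose-rate mice needs no control pool and sets 6 mice against 6. No gene passed with limma (smallest adjusted p = 0.0586), while 1127 had an unadjusted p under 0.05 against 561 by chance. Nearest were Xrn2, a nuclear exonuclease (0.44 ± 0.08, adjusted p = 0.0586, higher in 6 of 6 mice), Banp (-1.34 ± 0.23) and the transcription factor Foxo4 (-0.71 ± 0.13), both with adjusted p = 0.0586 and lower in 6 of 6 mice. Rnf125 was 0.41 ± 0.08 and Mindy2 0.50 ± 0.10 higher (adjusted p = 0.0852 for each), Ppp1r3c, a glycogen-targeting phosphatase subunit, was 0.90 ± 0.18 (adjusted p = 0.0966), and Esrp2 was 0.38 ± 0.08 (adjusted p = 0.111). Lurap1l was -0.72 ± 0.14 (adjusted p = 0.0768), Ccdc117 -0.69 ± 0.14 (adjusted p = 0.0966) and Angptl4 -0.98 ± 0.21 (adjusted p = 0.129). Each of these 10 genes had the same direction in 6 of 6 high mice, each set against the mean of the low mice of its experiment. With no filter Angptl4 was read from another probe set, which went the opposite way. The count of 0 rose to 17 without low mouse 3 of experiment 2, to 7 without low mouse 3 of experiment 1 and to 1 without high mouse 1 of experiment 1 or high mouse 3 of experiment 2. Other fits gave up to 4 genes (every probe set on its own), and a threshold of 0.10 gave 8, 4 in each direction.

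Cholesterol synthesis genes had the most members past the threshold adjusted over a list alone in high against low mice. The list was called higher (17 of 20, median 0.44, adjusted p = 5.3e-10; adjusted p = 0.52 with an estimated correlation), and 12 members passed adjusted over the list alone, all higher, with 0 over all genes. Sqle was 1.59 ± 0.37, Idi1, isopentenyl-diphosphate isomerase, 0.76 ± 0.19, Fdft1, squalene synthase, 0.66 ± 0.16 and Hmgcs1 0.50 ± 0.13, each higher in 6 of 6 mice. Of 23 targets of p53 and the DNA damage response, 17 were higher (median 0.25, adjusted p = 0.00036; adjusted p = 0.32 with an estimated correlation), and 8 passed adjusted over the list alone, 7 higher and 1 lower. The proapoptotic gene Bbc3 was 0.61 ± 0.18 and Phlda3 0.66 ± 0.22, higher in 6 of 6 mice, and the cell cycle inhibitor Cdkn1a was 0.90 ± 0.29 and Ddit4l 0.87 ± 0.29, higher in 5 of 6. Plk3 was the member that was lower (-0.96 ± 0.34, named after its value was seen). Fry found change in either direction in this list (mixed, adjusted p = 0.00089) and no common direction (adjusted p = 0.073). The p53 list was not called against control at any dose-rate. Interferon response genes were called higher in high against low mice (29 of 32, median 0.30, camera adjusted p = 2.3e-08, or 0.7 with an estimated correlation). The immunity-related GTPases Irgm1 (0.50 ± 0.15), Irgm2 (0.54 ± 0.18) and Igtp (0.50 ± 0.17) were above the low mean of their experiment in 6 of 6 mice. Low mouse 3 of experiment 1 still lay above high mouse 3 for Irgm1 and Igtp. No member of the list passed adjusted over the list alone, and 12 had an unadjusted limma p under 0.05. Heat shock genes were called lower (16 of 20, median -0.16, adjusted p = 0.00023; adjusted p = 0.7 with an estimated correlation), and Hspa1b (-1.87 ± 0.41), Dnajb1 (-0.74 ± 0.18), Bag3 (-0.62 ± 0.20) and Hspa1a passed adjusted over the list alone, each lower in 6 of 6 mice. Hspa1a had a mean signal of 54.6 in high mice, not shown to be above background, so its size is not given.

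**Figure D3:**
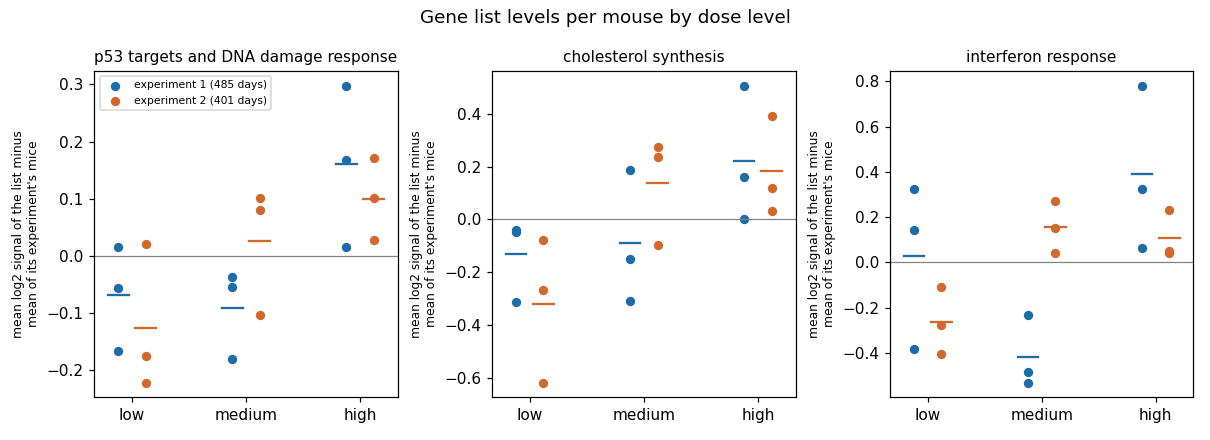
Mean log2 signal of 3 gene lists in each irradiated mouse, relative to the mean of the mice of its experiment, by dose level. Circles are mice, bars are means of 3 mice, and the colour gives the experiment. The p53 target list averaged 0.16 and 0.10 in high mice and -0.07 and -0.13 in low mice of experiments 1 and 2.

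Sex-biased and lipid genes were called in the same comparison. Female-biased liver genes were higher (14 of 16, median 0.59, or 0.36 without low mouse 2 of experiment 2, adjusted p = 0.00031; adjusted p = 0.7 with an estimated correlation), with the peroxisomal transporter Abcd2 (1.22 ± 0.36) past the threshold adjusted over the list alone, and male-biased genes were lower (16 of 17, median -0.37, or -0.22 without high mouse 2 of experiment 1, adjusted p = 0.00027; adjusted p = 0.7 with an estimated correlation), with C6 at -0.82 ± 0.34. Fatty acid oxidation and PPAR alpha targets (median 0.13, adjusted p = 0.00031) and fatty acid synthesis genes (median 0.21, adjusted p = 0.00035; 0.08 without low mouse 2 of experiment 2, and 0.08 with adjusted p = 0.0788 in experiment 1 alone) were called higher (adjusted p = 0.7 with an estimated correlation for both). Pdk4 (0.76 ± 0.25) and Cyp4a14 (0.66 ± 0.20) were above the low mean of their experiment in 6 of 6 mice, and Pnpla3 was 1.21 ± 0.43. In experiment 2, low mouse 3 lay above high mice 2 and 3 for Pdk4 and above every high mouse for Cyp4a14. The 1 member of the fatty acid oxidation list past the threshold adjusted over the list alone, Angptl4, went against the list (-0.98). ER stress genes (median -0.13, adjusted p = 0.004; adjusted p = 0.76 with an estimated correlation; Chac1 -0.55 ± 0.20) and acute phase genes (median -0.25, adjusted p = 0.0063; adjusted p = 0.88 with an estimated correlation; Orm3 -1.48 ± 0.65) were called lower. The signal of Orm3 was 1752.1 in low mouse 1 of experiment 1 and 19.7 to 223.2 in high mice. In experiment 2 alone Orm3 was not lower, so its size is uncertain. Hepatocyte markers (median 0.08, adjusted p = 0.016; adjusted p = 0.83 with an estimated correlation) and oxidative phosphorylation (median 0.05, adjusted p = 0.00036; adjusted p = 0.88 with an estimated correlation) were called higher, with the urea cycle enzyme Ass1 (1.05 ± 0.25) past the threshold adjusted over the list alone and Ndufc2 at 0.20 ± 0.08. The probe set used for Ass1 had signals of only 163.4 to 668.4, against 70068.9 or more for the hepatocyte marker Apoa1. Whether it reports the main Ass1 transcript is not shown. The clock list was not called as a whole (median -0.10, mean 0.00, camera direction up, adjusted p = 1), while fry found change in either direction (mixed, adjusted p = 0.00048) and 3 members passed adjusted over the list alone, with the smallest p for Per1 (lower) and Nfil3 (0.54 ± 0.15). The acute phase call ended without low mouse 1 of experiment 1 (median -0.03, adjusted p = 0.909), as did that for oxidative phosphorylation (median 0.02, adjusted p = 0.518). Without high mouse 2 of experiment 1 the calls for hepatocyte markers (median 0.04, adjusted p = 0.21) and oxidative phosphorylation (median 0.02, adjusted p = 0.232) ended. Hepatocyte markers also lost theirs without high mouse 3, low mouse 1 or low mouse 3 of experiment 1, and ER stress genes without high mouse 1, low mouse 1 or low mouse 2 of experiment 2 (adjusted p up to 0.146). In experiment 1 alone the male-biased list was not called (median -0.28, adjusted p = 0.11), and in experiment 2 alone neither were the acute phase list (-0.09, 0.271) and the PPAR alpha list (0.05, 0.518). In experiment 2 alone the test directions of hepatocyte markers (median -0.07, adjusted p = 0.113) and oxidative phosphorylation (median 0.00, adjusted p = 0.642) turned to lower. In experiment 1 alone the test direction of ER stress genes turned to higher (median -0.03, adjusted p = 0.866), and the quantile-normalized arrays ended the calls for hepatocyte markers (adjusted p = 0.809) and oxidative phosphorylation (adjusted p = 0.13).

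Between high and medium dose-rate mice no gene passed with limma (smallest adjusted p = 0.412), and 431 had an unadjusted p under 0.05, against 561 by chance. The histone gene H2bc22 had a signal of 526.4 ± 142 in high and 201.6 ± 112.1 in medium mice (SD, n = 6 each). It was higher in 6 of 6 mice, as was the clock-linked repressor Nfil3 (0.73 ± 0.15), and Ccdc93 (-0.51 ± 0.11) was lower in 6 of 6 (limma adjusted p = 0.412 for each). Gm6958 was 0.92 ± 0.21, Dpy19l3 -0.81 ± 0.19 and Ctnnbl1 -0.38 ± 0.10. Interferon response genes were called higher (31 of 32, median 0.31, adjusted p = 6.1e-16; adjusted p = 0.58 with an estimated correlation), with Gbp3 at 0.83 ± 0.25. In experiment 2 alone this list turned to lower (adjusted p = 0.601), and none of the other 7 lists named next was called there, with adjusted p from 0.177 for Kupffer cell markers to 0.96 for fatty acid oxidation and medians of 0.04 for p53 targets, 0.004 for cholesterol synthesis and 0.01 for fatty acid oxidation. In experiment 1 alone Kupffer cell markers (adjusted p = 0.131) were not called. Further lists called higher were p53 targets (median 0.16, adjusted p = 0.0034; adjusted p = 0.45 with an estimated correlation; Plk2 0.37 ± 0.14), cholesterol synthesis (0.17, 0.0034; Sqle 0.85 ± 0.37), fatty acid oxidation and PPAR alpha targets (0.08, 0.0034; Cyp4a14 0.59 ± 0.20), female-biased genes (0.33, 0.0059; Fmo2 0.68 ± 0.20), Kupffer cell markers (0.19, 0.027; C1qb 0.31 ± 0.16) and fatty acid synthesis (0.05, 0.048; Aacs 0.56 ± 0.15). Male-biased genes were called lower (median -0.22, adjusted p = 0.0083; Cspg5 -0.56 ± 0.28). These calls were lost with an estimated correlation as well (adjusted p = 0.89 for fatty acid synthesis and 0.78 for the others). Aacs was the 1 member of any called list past the threshold adjusted over the list alone. Apart from the interferon list, each of these calls ended without 1 or more single arrays, with adjusted p up to 0.481 for fatty acid synthesis without high mouse 2 of experiment 1 (median 0.005). Without that mouse the medians of male-biased genes and of fatty acid oxidation were -0.12 and 0.05. Smallest medians were 0.08 for cholesterol synthesis without high mouse 3 of experiment 1, 0.20 for female-biased genes without high mouse 3 of experiment 2 and 0.10 for Kupffer cell markers without high mouse 2 of experiment 2.

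Between medium and low dose-rate mice no gene passed either (smallest adjusted p = 0.299, limma), and 889 had an unadjusted p under 0.05. Pde4b, a cyclic AMP phosphodiesterase, was 1.08 ± 0.23, Tbcel 0.35 ± 0.07 and Bhmt, which remethylates homocysteine, 0.29 ± 0.06 higher. Nop58, a nucleolar protein, was -0.65 ± 0.13 and H2bc22 -1.32 ± 0.30 (adjusted p = 0.299 for all 5, the same direction in 6 of 6 mice). Lurap1l was -0.58 ± 0.14 (adjusted p = 0.345), with another probe set in the opposite direction. Cholesterol synthesis genes were called higher (16 of 20, median 0.25, or 0.16 without low mouse 2 of experiment 2, adjusted p = 0.00011; adjusted p = 0.77 with an estimated correlation), with Nsdhl at 0.44 ± 0.16 and Lss at 0.47 ± 0.18. Its median was 0.04 in experiment 1 alone (adjusted p = 0.782) and 0.40 in experiment 2 alone (adjusted p = 1.83e-08). Heat shock genes (median -0.23, adjusted p = 0.00016; Hspa4l -0.28 ± 0.10), Kupffer cell markers (15 of 16 lower, median -0.20, or -0.13 without medium mouse 3 of experiment 2, adjusted p = 0.00016; Cd5l -0.39 ± 0.14) and ER stress genes (median -0.12, or -0.06 without medium mouse 2 of experiment 2, adjusted p = 0.0015; Chac1 -0.62 ± 0.20) were called lower (adjusted p = 0.77 with an estimated correlation for all 3). Hepatocyte markers (median 0.10, adjusted p = 0.00072; adjusted p = 0.77 with an estimated correlation; Apoa1 0.21 ± 0.06) and oxidative phosphorylation (median 0.05, adjusted p = 0.03; adjusted p = 0.88 with an estimated correlation) were called higher. With quantile normalization the hepatocyte markers list, medium against low, had an adjusted p of 0.784 and the oxidative phosphorylation list, medium against low, 0.912. No member of these 6 lists passed adjusted over the list alone, and unadjusted limma p values under 0.05 were held by 7 cholesterol synthesis, 5 heat shock, 4 Kupffer cell, 4 ER stress, 3 hepatocyte and 2 oxidative phosphorylation genes. Without low mouse 1 of experiment 1 the test direction of oxidative phosphorylation turned to lower (median 0.01, adjusted p = 0.917), and without low mouse 2 of experiment 2 ER stress genes had an adjusted p of 0.0969. ER stress genes in experiment 1 alone (adjusted p = 0.0716) and, in experiment 2 alone, hepatocyte markers (0.27) and oxidative phosphorylation (0.994) were not called.

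Whether an effect differed between the experiments was tested as an interaction. For high against control, Cela3b, a pancreatic elastase, passed (-3.62 ± 0.53, adjusted p = 0.0222, limma), with a difference of 3.30 in experiment 1 and -0.33 in experiment 2. Its signal was 7.9 in the pool of experiment 1 and 94.7 or more on the other 19 arrays, so this size rests on 1 pool value not shown to be above background. Spen (-3.30 ± 0.56, adjusted p = 0.0655, signal 9.5 in the pool of experiment 1) and Hnrnpab (-1.77 ± 0.31, adjusted p = 0.0779) did not pass, and all 4 other probe sets of Hnrnpab went the opposite way. An unadjusted p under 0.05 was held by 431 genes. For high against low no gene passed (smallest adjusted p = 0.14), and 777 had an unadjusted p under 0.05. The nearest were Zcchc2 (-1.65 ± 0.28, adjusted p = 0.14), the MHC class II gene H2-Eb1 (1.42 ± 0.26, adjusted p = 0.187) and Gnat1 (adjusted p = 0.348), whose mean signal of 52.2 in low mice of experiment 2 is not shown to be above background. The difference of H2-Eb1 between high and low mice was -0.70 in experiment 1 and 0.71 in experiment 2. The call of Cela3b ended, with adjusted p from 0.05 to 0.0716, when high mouse 2 or 3 of either experiment or medium mouse 2 of experiment 2 was left out.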

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

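Among the tests in this part, those of killing time and dose-rate for the clock genes, of 1 mouse and dose-rate for the p53 targets, and of 1 mouse and leukocytes for the interferon genes were chosen only after the result was seen, and the splits of these 2 lists after their calls.

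Differences between the 2 experiments in the effect of the high dose-rate, by a test of the interaction itself, brought the following results here. Cela3b differed by -3.62 ± 0.53 between experiments (adjusted p = 0.0222, limma), with a signal of 7.9 in the control pool of experiment 1 and 156.3 in that of experiment 2. Pancreatic acinar markers, 4 genes that include Cela3b, differed by a median of -0.88 (camera adjusted p = 0.013; adjusted p = 0.27 with an estimated correlation). The interferon response list differed by -0.57 (camera adjusted p = 1.3e-08, or 0.91 with an estimated correlation). For 29 of 32 genes the high-minus-control difference was lower in experiment 2 than in experiment 1. The list was still higher than control in experiment 2 alone (median 0.17). Acute phase genes differed by -0.31 (adjusted p = 0.012; adjusted p = 0.93 with an estimated correlation). Hepatocyte markers differed by -0.30 (adjusted p = 4.4e-05; adjusted p = 0.91 with an estimated correlation).

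In high against low mice, 7 MHC class II genes differed between experiments by a median of 1.36 (adjusted p = 3e-08; adjusted p = 0.4 with an estimated correlation), and 4 passed adjusted over the list alone, with H2-Ab1 at 1.45 ± 0.33 and Cd74 at 1.36 ± 0.35. Low mice 1 and 3 of experiment 1, at 0.35 and 0.87 for this list, were also high for monocyte (0.77 and 0.79), T cell (0.62 and 0.37) and Kupffer cell markers (0.29 and 0.30). Hepatocyte markers differed by -0.26 (adjusted p = 2.1e-08; adjusted p = 0.43 with an estimated correlation), with Alb at -0.52 ± 0.12 among 6 genes that passed adjusted over the list alone. ER stress genes differed by -0.31 (adjusted p = 0.0017; adjusted p = 0.89 with an estimated correlation), with Herpud1 and Dnajb9 past the threshold adjusted over the list alone. Oxidative phosphorylation differed by -0.16 (adjusted p = 8.9e-07), fatty acid oxidation and PPAR alpha targets by -0.15 (adjusted p = 0.02) and stellate cell markers by 0.27 (adjusted p = 0.014), each with adjusted p = 0.89 with an estimated correlation.

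The means of 2 groups of clock genes lay apart from each other, relative to the control pools, in every irradiated mouse. The mean of 5 genes grouped with Arntl minus the mean of 9 grouped with Dbp was 0.73 above the pools in low, 0.96 in medium and 1.43 in high mice, or 0.47, 1.01 and 1.36 in experiment 1 and 0.99, 0.91 and 1.5 in experiment 2, where medium lay below low. Arntl itself lay above the pools in all 18 mice. Nfil3 lay below them in every low mouse (-0.069 to -1.065) and above them in high mice of experiment 2 (0.277 to 0.416). Npas2 was -0.18 to -1.136 in low mice of experiment 1 and 1.12 to 1.429 in those of experiment 2. Clock and Cry1 went both ways, so the 5 genes did not move as 1 group. With irradiated mice of a group averaged on the linear scale, at least 0.97 of the difference remained. This argues against averaging in the pools as the source if the control mice varied like the irradiated mice. The spread among the control mice of a pool was not measured, so averaging is not excluded. A time of killing or feeding that differed between control and irradiated mice could give the same pattern, and it cannot be told apart from radiation, since the smallest difference among the 18 mice was 0.28 and the killing time is not in the labels. Dose-rate could contribute, since high exceeded low by 0.70 (95% interval 0.25 to 1.15, exact two-sided p = 0.005, the smallest that 400 relabelings can give). Killing or feeding times that differed between dose levels could give this difference as well, so it cannot be assigned to dose-rate. The clock list as a whole was not called in high against low, and the test of this difference was chosen after the result was seen.

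Targets of p53 were higher in high than in low mice by 0.23 in the list mean (95% interval 0.09 to 0.36, exact two-sided p = 0.01). The list was not called against control at any dose-rate. Its median relative to the irradiated mice of the same experiment was -0.03 and -0.01 in the control pools. A rise over unirradiated mice is therefore not shown. No single left-out array ended the camera call for high against low at the preset correlation (highest adjusted p = 0.00525). The list's median was 0.205 at the least, without high mouse 1 of experiment 1. The call was lost with an estimated correlation, so these values do not exclude a contribution of 1 mouse. The list's median stayed at 0.25 or more against all genes with median centring and with quantile normalization. A shift common to all genes of an array moves the list and all genes alike, so median centring could not change that value. The median of all genes in this contrast was 0 as deposited and -0.004 and -0.001 with these scalings. These values argue only against a uniform scale difference of the list's size, and other effects of scaling cannot be told. Of 100 splits of the mice, the real one included, 3 gave as large a mean t (real value 1.2, highest other 1.29), but the list was picked among 12 called lists, so chance is not excluded. Dose-rate may contribute but cannot be told apart from a step at the high level, since the medium mean lay between low and high in 1 of 2 experiments.

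Interferon response genes were higher in high than in low mice by 0.37 in the list mean (95% interval -0.03 to 0.76, exact two-sided p = 0.03). Medium mice did not follow dose-rate, at -0.42 against 0.03 in low and 0.39 in high mice of experiment 1 and at 0.16 against -0.26 and 0.11 in experiment 2. No single left-out array ended the camera call at the preset correlation (highest adjusted p = 8.1e-05). The list's median was 0.301, or 0.211 without high mouse 2 of experiment 1. The call was lost with an estimated correlation, so these values do not exclude a contribution of that mouse. More leukocytes in the samples could raise such genes and cannot be told apart from induction, since 49 leukocyte markers differed by -0.10 with an upper limit of 0.20. Of 100 splits, the real one included, 3 gave as large a mean t (real value 1.59, highest other 2.06), but the list was picked among 12 called lists, so chance is not excluded.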

How the results depend on the processing

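Among the tests in this part, those of lists with an array left out, in 1 experiment alone and with median-centred arrays were chosen only after the results were seen. Over all alternatives, 6970 of 7208 values of named genes kept their direction and side of the threshold, 78 were weaker, 153 stronger and 7 reversed, and of 1215 list values 1016 were the same, 192 weaker and 7 reversed. Causes were not tested unless stated. Low signal over background limits the genes near the filter. Counts below are in the order high, medium and low against control unless named. With no filter the low count and the interaction count for high against control were 0, the 1.5-fold rule gave 166, 197 and 150 genes, and Angptl4, read from another probe set, was 0.42 in medium against control and 0.15 in high against low, reversed. With the top 30% of probe sets the low count and that interaction were 0, the fold rule gave 15, 9 and 2, and Ssr4, read from another probe set, was -0.18 in high and -0.014 in low against control. Without a pseudocount that interaction gave 2 genes and Adamts5 in medium mice, read from another probe set, was -0.21. With the 25th percentile as pseudocount the low count and that interaction were 0 and the fold rule gave 19 in medium and 8 in low. Median-centred arrays gave 3 and 1 genes in high and medium against control and 1 in high against low. Quantile normalization gave 1 in high against low, 2 in that interaction and 10 in low by the fold rule. Every probe set on its own gave 13 and 8 in high and medium, 4 in high against low, 7 and 1 in the interactions for control and for low, and 109, 87 and 50 by the fold rule. Of those called, 1 of 13 in high and 2 of 7 in the interaction had no single gene name. Only the 2 levels compared gave 15, 9 and 0. No experiment term gave 3 in high, all of them higher. Experiment 1 alone gave 0, 0 and 0, and Dnajb9 in high against low was 0.047. Experiment 2 alone gave 0, 0 and 0 and 1 in high against low, where Orm3 was 0.041. Array weights gave 12, 8 and 2 and 1 in high against low. A threshold of 0.10 gave 5 in medium and 8 in high against low. Without a variance trend the counts were 3 in high, 1 in medium and 2 in high against low. Pools weighted by their mice gave 360 (205 higher, 155 lower), 260 (144 and 116) and 56 (34 and 22). The mice are not paired by the labels. A fixed replicate block gave 1 in high against low, and a random block left 6, 3 and 1 (consensus correlation 0.075). Of 18 mice, 14 correlated best with a mouse of their own number. Only a minority of the mice each was compared with shared its number, so this is more than random matching would give. Something shared by mice of 1 number is not excluded, and the splits and exact tests treated the mice of an experiment as exchangeable. A 2-fold rule gave 6, 4 and 3, and a rule of at least 5 of 6 mice 139, 116 and 79.

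With each array left out in turn, limma gave 1 to 24 genes in high, 1 to 22 in medium and 0 to 12 in low against control. It gave 0 to 17 in high against low and 0 to 0 in high against medium and in medium against low. In the interactions for control and for low it gave 0 to 3 and 0 to 2. In limma without 1 pool, the lone remaining pool was assumed to vary like the mice. The fold rule gave 55 to 523, 41 to 420 and 21 to 385 genes. It then covered fewer than 6 mice, since each mouse is set against the pool of its own experiment. The highest counts, without the experiment 2 pool, rest on the 3 mice of experiment 1. These counts are therefore not comparable with those over all 6 mice. By limma the fewest in high and medium against control came without the experiment 1 pool and the most without the experiment 2 pool. Medium against control gave 5 without low mouse 2 of experiment 1 or high mouse 1 of experiment 2. Low against control gave 3 without low mouse 1 of experiment 1, 2 without low mouse 3 of experiment 2, and 0 without medium mouse 1 or 3 of experiment 1 or low mouse 2, medium mouse 1 or 2 or high mouse 2 or 3 of experiment 2. The interaction for control gave 3 without medium mouse 1 or high mouse 1 of experiment 1, 2 without medium mouse 3 of either experiment, and 0 without high mouse 2 or 3 of either experiment or medium mouse 2 of experiment 2. The interaction for low gave 2 without low mouse 2 of experiment 1 or low mouse 3 of experiment 2 and 1 without medium mouse 1 or 3 of experiment 1. For Angptl4, high against control, the call was lost without the experiment 1 pool (adjusted p = 0.63), the experiment 2 pool (0.114), high mouse 2 of experiment 1 (0.0916), high mouse 2 or 3 of experiment 2 (0.0637 and 0.0697), medium mouse 1 or 2 of experiment 1 (0.0572 and 0.0516), medium mouse 2 of experiment 2 (0.0591) or low mouse 3 of experiment 2 (0.0561). For Lpin2, high against control, it was lost without the experiment 1 pool (0.856) or high mouse 1 or 3 of experiment 2 (0.053 and 0.0697).

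Of 900 leave-one-out list values 831 were the same, 68 weaker and 1 reversed, of 90 from 1 experiment 59, 26 and 5, and of 135 from filter and scaling 121, 13 and 1. With an estimated correlation 2 of 45 calls were the same and 43 weaker, and with fry 3 and 42. Lists that reversed were hepatocyte markers in medium against control with quantile normalization (adjusted p = 0.925), cholesterol synthesis in medium against control in experiment 1 alone (0.844), ER stress in high against low in experiment 1 alone (0.866), hepatocyte markers (0.113) and oxidative phosphorylation (0.642) in high against low and interferon response in high against medium (0.601) in experiment 2 alone, and oxidative phosphorylation in medium against low without low mouse 1 of experiment 1 (0.917, over left-out arrays 0.000304 to 0.917). The direction is that of the test.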

Other observations

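None of the tests in this part was chosen after the result was seen.

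Bile acid genes moved in both directions between high and low mice. The list of 21 genes was not called (camera adjusted p = 0.75), while fry found change in either direction (mixed, adjusted p = 0.0016). Of 4 genes past the threshold adjusted over the list alone, 3 higher and 1 lower, the smallest p belonged to the sterol transporter gene Abcg8 (-0.45 ± 0.11) and to Cyp8b1, the sterol 12-alpha-hydroxylase (0.97 ± 0.25). In medium against low mice, Hmox1, heme oxygenase, was -0.59 ± 0.14 and passed adjusted over the list of antioxidant genes alone.

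Some single arrays stood apart in list medians relative to the irradiated mice of their experiment. High mouse 2 of experiment 1 had 0.81 for interferon response, -0.94 for male-biased and 0.73 for female-biased genes. Low mouse 1 of experiment 1 had 1.00 for acute phase genes and 1.62 for neutrophil markers. Low mice 1 and 2 of experiment 2 had 0.40 and 0.77 for male-biased and -0.58 and -0.95 for female-biased genes.

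Splits of the mice into groups that ignore dose tested whether chance can be excluded, with the real split counted among the 100. For high against low it could not be excluded for the genes at an unadjusted p under 0.05, since 7 of 100 splits had as many (real 1127, highest other 1734), nor for the lists, with 33 splits (12, highest other 21). For the interaction with low it could not be excluded, with 26 splits (777, highest other 1345). For high against medium 51 splits had as many genes (431, highest other 1036) and 18 as many lists (8, highest other 13), and for medium against low 19 had as many genes (889, highest other 1441) and 72 as many lists (6, highest other 20), so chance could not be excluded there either. Of the splits for high against low, 10 gave genes past the adjusted threshold, up to 47, against 0 in the real split, and the cause was not tested.

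The averaging of several mice in the control pools could shift genes that vary between mice. Over the 1122 most variable genes, the median difference from the pools was -0.05 on the log scale and 0.06 with mice averaged on the linear scale, and whether averaging contributed cannot be told.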
